A study of Escherichia coli with 55 samples.

How the data were processed

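The study measured messenger RNA levels in Escherichia coli K-12 MG1655 on two-colour spotted arrays. Per the labels, the RNA of each test culture was labelled with Cy5 and hybridised together with Cy3-labelled RNA pooled from wild-type cultures, which served as a common reference. In a set of 31 arrays the pool came from cultures grown without oxygen (the anaerobic reference set), and in a further set of 24 arrays it came from cultures grown with oxygen (the aerobic reference set). Per the labels, pools were made from at least 4 cultures, test RNA came from 3 independent cultures per group, RNA was stabilised and column-purified with DNase digestion, and its quality was read on a Bioanalyzer. Per the series' design text, cells grew on glycerol with trimethylamine-N-oxide (TMAO) and fumarate, a medium in which a mutant lacking the regulator FNR grows as well as its parent. The same text gives the purpose of the aerobic pool as a check on genes repressed by FNR, whose signal in an anaerobic pool can be weak.

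The deposited values are log2 ratios of Cy5 over Cy3, 1 per spot and array, so a positive value means more RNA in the test culture than in the pool. The log2 scale, the direction and the lack of centring were read from the deposited values together with the dyes in the labels. The values were not centred, since the array medians of named genes ran from -0.62 to 0.83 in the anaerobic reference set and from -1.22 to 0.60 in the aerobic reference set. The scanner, the background correction and any normalization within arrays are not given in the sources used here, and neither are spot intensities, so no background test of single spots was made and the number of arrays sets the precision. A value of 16.61 stood apart from all others, of which the highest was 9.04 in the anaerobic and 8.83 in the aerobic reference set, and was taken as a ceiling and treated as missing.

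Spots were named through the platform annotation. Of 14400 spots in the anaerobic reference set, 6412 had 1 gene name, 48 had several and 7940 were not listed. The named spots gave 3204 genes, of which 3196 matched the gene table of assembly ASM584v2, used for names alone. Of 14400 spots in the aerobic reference set, 9012 had 1 gene name, 0 had several and 5388 were not listed, which gave 4148 genes, 4123 of them matched. The heat shock gene dnaK was listed for 314 of these spots. Among the values of named spots, 0.592% were missing or at the ceiling in the anaerobic and 0.4% in the aerobic reference set. A gene's value on an array was the mean over its spots after the array median was subtracted, and a comparison tested genes with at least 2 values in each of its groups.

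Groups were taken from the labels. The wild type and the fnr mutant were each grown with oxygen, without oxygen, without oxygen plus nitrite and without oxygen plus nitrate, with 3 arrays per group in each set. The anaerobic reference set also held 4 arrays of a mutant labelled as lacking narX and narL and 3 arrays of a mutant labelled as lacking narX, narL and narP, all grown without oxygen plus nitrite. The labels leave several points open. Sample descriptions in the anaerobic reference set carry text on an aerobic pool, although their channel labels name the anaerobic reference. For wild type anaerobic replicate 1 of the aerobic reference set a channel characteristic names anaerobic growth of the pool, and replicate 3 there lacks a genetic background of its own. The titles of the narX narL mutants give no growth condition, which was read from the source name. The labels do not say whether the same RNA was hybridised to both references, nor how the 4 narX narL arrays came from 3 cultures, so 2 of these arrays may share a culture. The series title names narQ and narP where the sample labels name narX, narL and narP, which were followed here, and the descriptions of both nar mutants speak of fnr mutant RNA.

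Within each set, limma 3.58.1 (R 4.3.3) fitted 1 mean per group with lmFit over all arrays, and comparisons were contrasts of these means with moderated tests from eBayes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes at an adjusted p under 0.05 were called. A second count took called genes that changed at least 2-fold, a log2 change of 1. The sets were fitted separately and never pooled. Comparisons were anaerobic minus aerobic growth in each strain, fnr mutant minus wild type with and without oxygen, nitrate or nitrite minus neither in each strain, the differences of these effects between strains, nitrate minus nitrite, and each nar mutant minus the wild type or minus each other with nitrite. Errors after a log2 change are standard errors from this fit (SE), and those after a log2 ratio to the pool are standard deviations (SD).

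The gene lists, the comparisons, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named the targeted genes fnr, narX, narL and narP together with narQ. It then took the 8 largest rises and falls of 7 comparisons and the 3 largest each way of the others, among genes called in the anaerobic reference set and, where both sets held the comparison, also called with the same sign in the aerobic reference set. For each list described it took up to 4 members, called ones with the largest changes first. The 28 lists were nitrate reductase A and nitrate transport, periplasmic nitrate reductase with cytochrome c maturation, the periplasmic nitrite reductase Nrf, the NADH-dependent nitrite reductase, formate dehydrogenase N, fumarate respiration with C4-dicarboxylate transport, dimethyl sulfoxide (DMSO) and TMAO reductases, hydrogenases 1 and 2, formate hydrogenlyase, nickel transport, anaerobic glycerol 3-phosphate dehydrogenase, glycerol uptake with the aerobic dehydrogenase, mixed-acid fermentation, NADH dehydrogenases, cytochrome bo oxidase, cytochrome bd oxidases, the tricarboxylic acid (TCA) cycle, nitric oxide and nitrosative stress, molybdenum cofactor and molybdate transport, iron-sulfur cluster assembly, iron uptake, ferrous iron transport, oxidative stress defence, acid resistance, ribosomal proteins, flagella and chemotaxis, heat shock, and other genes activated by FNR in enterobacteria. List members were counted when called over all genes and when adjusted over the list alone. Lists were tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, both from limma.

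The fit was tested on simulated data with known changes. For nitrate in the wild type (anaerobic reference, 3192 genes), 68% of 100 genes changed by a log2 of 1 were called. So were 87.8% of 98 changed by 2 and 5 of 2982 unchanged genes. The narX narL narP mutant against the wild type (3198 genes) gave 59%, 93% (100 each) and 9 of 2986. Nitrate in the wild type against the aerobic pool (4147 genes) gave 62%, 95% (100 each) and 3 of 3935. These rates need not hold for real arrays, where a wrong split of the first comparison called 1251 genes.

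Alternatives were arrays scaled to equal spread, ratios without centring, quantile normalisation, looser and stricter handling of missing values, a test per spot, the replicate number as a block, a fit of the compared groups alone, an estimated correlation in list tests, and each array left out in turn. A pair of further alternatives, keeping 1 wild type anaerobic array and leaving out flagella genes, was chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for summaries and plots.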

Results

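The transcriptome of Escherichia coli K-12 was measured under changes of oxygen, nitrate and nitrite, and in strains lacking FNR, the oxygen-sensing activator of anaerobic genes, or, by the sample labels, the nitrate and nitrite regulators NarX, NarL and NarP. The anaerobic reference set held 31 arrays in 10 groups and the aerobic reference set 24 arrays in 8 groups. Each group had 3 arrays, except the narX narL mutant with 4. All test values below come from limma with Benjamini-Hochberg adjustment. The SE follows each log2 change, and values are from the anaerobic reference set unless the aerobic reference set is named.

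The targeted genes were read first. The fnr transcript stood at a log2 ratio to the pool of -6.62 ± 0.34 to -7.90 ± 0.78 (SD, n = 3 per group) in the fnr mutant groups, against -0.40 ± 0.54 to 0.53 ± 0.25 in the other strains (n = 3 or 4). It lay, against the aerobic pool, between -3.12 ± 0.91 and -3.89 ± 0.70 in the mutant and between -0.74 ± 0.48 and 0.49 ± 0.32 in the wild type (n = 3 per group). With nitrite, narL, which encodes the response regulator of the NarX sensor, was at 1.85 ± 0.27 in the wild type (n = 3), at -5.81 ± 0.92 in the narX narL mutant (n = 4) and at -6.79 ± 1.05 in the narX narL narP mutant (n = 3). The narX values of the same groups were 1.43 ± 0.32, -2.73 ± 0.37 and -2.72 ± 1.00. For narP, the gene of a second response regulator, they were -0.07 ± 0.18, -0.44 ± 0.19 and -1.03 ± 0.18. The fall in the triple mutant (log2 change -0.97 ± 0.19, adjusted p = 0.00203) was small beside that of narL. Intact strains grown with oxygen read lower for narP, at -1.90 ± 0.17, so these spots do not check its deletion. The series title names narQ and narP in place of narX, narL and narP, so the genotype of the triple mutant beyond narX and narL rests on its labels. The sensor gene narQ was at 0.43 ± 0.25 and 0.41 ± 0.16 in the 2 nar mutants and at 0.20 ± 0.17 in the wild type with nitrite.

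Growth without oxygen was compared with growth with oxygen in the wild type. Anaerobic cells held far more RNA of genes for anaerobic respiration and far less of genes for aerobic respiration. Both reference sets gave the same sign for each gene named here with 2 values (n = 3 arrays per group and set). The C4-dicarboxylate exchanger gene dcuB rose by a log2 of 5.78 ± 0.33, and by 3.99 ± 0.42 in the aerobic reference set. The anaerobic fumarase gene fumB rose by 5.76 ± 0.32 and 3.79 ± 0.37, the asparaginase gene ansB by 6.23 ± 0.33 and 4.70 ± 0.47, and ydfZ, known as FNR-activated, by 5.85 ± 0.26 and 3.59 ± 0.39. Among the falls, the manganese superoxide dismutase gene sodA changed by -6.45 ± 0.32 and -5.32 ± 0.47, and the cytochrome bo oxidase genes cyoA, cyoB and cyoC by -6.27 ± 0.31, -5.85 ± 0.35 and -5.15 ± 0.41. The trehalose uptake and cleavage genes treB and treC changed by -5.26 ± 0.45 and -5.01 ± 0.43. Glutamate decarboxylase genes gadB and gadA, which serve acid resistance, rose by 6.64 ± 0.79 and 6.58 ± 0.85, and by 2.89 ± 0.51 and 3.30 ± 0.70 in the aerobic reference set. Of 3190 genes tested, 681 were higher and 775 lower without oxygen, and 807 of them changed at least 2-fold. Without centring the split was 351 higher and 648 lower, while the median of all genes moved by -0.07. The total of 1456 was 864 at equal spread, 866 after quantile normalisation and 408 in a fit of these groups alone. Of 4147 genes in the aerobic reference set 140 were higher and 174 lower, and 33 higher and 67 lower without centring, which moved the median by -0.15. That total of 314 was 605 at equal spread, 620 after quantile normalisation and 130 in a fit of these groups alone. It was 164 and 151 without wild type aerobic replicates 2 and 3, and 621, 166 and 192 without wild type anaerobic replicates 1, 2 and 3. Genes called with the same sign in both sets numbered 84 higher and 142 lower, where independent lists would share 22.6 and 37.0. Such values make no allowance for RNA shared between the sets, which the labels leave open, and deviations of wild type anaerobic arrays correlated across genes between the sets at up to 0.651. None was called with opposite signs, but a test of the difference between the sets called 114 of 3188 genes.

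Most genes of the respiratory lists rose on anaerobic growth of the wild type, although against the anaerobic pool none of these 7 lists was called with an estimated correlation. All 5 genes of nitrate reductase A and nitrate transport rose (5 adjusted over the list alone), among them narG at 3.75 ± 0.33 and narK, the nitrate transporter gene, at 3.39 ± 0.38. The camera test gave an adjusted p = 4.28e-05, and an adjusted p = 0.0603 with an estimated correlation. For the periplasmic nitrate reductase with cytochrome c maturation, 12 of 13 genes rose (12 adjusted over the list alone), led by napC at 2.07 ± 0.20 and ccmC at 1.81 ± 0.20 (adjusted p = 5.27e-06, and adjusted p = 0.0828 with an estimated correlation). The nitrite reductase Nrf rose in 5 of 6 genes (5 adjusted over the list alone), with nrfC at 4.41 ± 0.38 and nrfA at 4.30 ± 0.28 (adjusted p = 4.77e-06, and adjusted p = 0.0543 with an estimated correlation). For the NADH-dependent nitrite reductase, nirB and nirD rose by 2.14 ± 0.38 and 2.09 ± 0.33, 2 of 3 genes tested (2 adjusted over the list alone; list adjusted p = 0.0512). Against the aerobic pool 0 of 4 of these genes were called by limma and the list median was -0.04, and narK, napC, ccmC and fdnH were not called either. All 3 genes of formate dehydrogenase N rose (3 adjusted over the list alone; adjusted p = 0.00284, and adjusted p = 0.0603 with an estimated correlation), led by fdnH at 3.16 ± 0.29. Fumarate respiration with C4-dicarboxylate transport rose in 9 of 11 genes (9 adjusted over the list alone; adjusted p = 2.3e-08, and adjusted p = 0.0543 with an estimated correlation) and held its call in the aerobic reference set with an estimated correlation (adjusted p = 0.0145). DMSO and TMAO reductases rose in 8 of 8 genes (8 adjusted over the list alone), with ynfH at 4.24 ± 0.28 and torA, the TMAO reductase gene, at 3.90 ± 0.37. Their list gave an adjusted p = 1.59e-07, an adjusted p = 0.0603 with an estimated correlation, and an adjusted p = 0.0403 with an estimated correlation in the aerobic reference set.

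Hydrogenases 1 and 2 rose in 19 of 20 genes (20 adjusted over the list alone), with the small-subunit gene hybO at 5.29 ± 0.37. The list gave an adjusted p = 3.17e-15 and an adjusted p = 0.0543 with an estimated correlation. Formate hydrogenlyase rose in 8 of 10 genes (9 adjusted over the list alone), with the formate dehydrogenase gene fdhF at 3.46 ± 0.24 (list adjusted p = 0.000286, and adjusted p = 0.16 with an estimated correlation). The anaerobic glycerol 3-phosphate dehydrogenase genes glpC, glpB and glpA rose by 2.55 ± 0.36, 2.41 ± 0.30 and 1.97 ± 0.34, 3 of 3 genes (3 adjusted over the list alone; adjusted p = 0.00278, and adjusted p = 0.122 with an estimated correlation). Mixed-acid fermentation rose in 6 of 10 genes (6 adjusted over the list alone), with the acetate kinase gene ackA at 1.55 ± 0.22 (list adjusted p = 0.00227, and adjusted p = 0.122 with an estimated correlation). Other FNR-activated genes rose in 9 of 12 (9 adjusted over the list alone), with ydhV at 4.38 ± 0.41 and the cytochrome c peroxidase gene ccp at 3.67 ± 0.37 (list adjusted p = 6.61e-07, and adjusted p = 0.0543 with an estimated correlation). Acid resistance rose in 10 of 13 genes (12 adjusted over the list alone; adjusted p = 1.02e-05, and adjusted p = 0.138 with an estimated correlation). It rose in 4 of 15 against the aerobic pool (9 adjusted over the list alone). Over the 13 genes in both sets its medians were 3.15 and 0.93, and 3 genes differed between the sets by test.

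Genes of aerobic respiration and ribosomal proteins were among the falls on anaerobic growth, although against the anaerobic pool none of these 6 lists was called with an estimated correlation. Not called against the aerobic pool were nuoE, rplW and katG. All 5 cytochrome bo oxidase genes fell (5 adjusted over the list alone; adjusted p = 2.05e-08, and adjusted p = 0.0543 with an estimated correlation), and the list kept its call in the aerobic reference set with an estimated correlation (adjusted p = 0.0308). The TCA cycle fell in 15 of 17 genes (15 adjusted over the list alone), with the succinate dehydrogenase genes sdhA and sdhC at -4.15 ± 0.35 and -3.92 ± 0.31 and the succinyl-CoA synthetase gene sucC at -3.84 ± 0.33. Its adjusted p = 7.96e-11 became an adjusted p = 0.0828 with an estimated correlation, and an adjusted p = 0.0308 with an estimated correlation in the aerobic reference set. NADH dehydrogenases fell in 10 of 11 genes (10 adjusted over the list alone), with nuoE at -2.03 ± 0.25 (list adjusted p = 6.61e-07, and adjusted p = 0.122 with an estimated correlation). Ribosomal protein genes fell in 51 of 54 (52 adjusted over the list alone), with rplW at -2.08 ± 0.26 (list adjusted p = 3.17e-15, and adjusted p = 0.201 with an estimated correlation). Their medians on the 3 wild type anaerobic arrays were -0.61, -0.07 and -1.52, and flagella medians on the same arrays were 0.02, 0.43 and -1.57. Iron-sulfur cluster assembly fell in 6 of 11 genes (6 adjusted over the list alone), with the ferredoxin gene fdx at -1.53 ± 0.20 (list adjusted p = 0.00508, and adjusted p = 0.211 with an estimated correlation). Oxidative stress defence fell in 5 of 10 genes and rose in 1, the catalase gene katG at 1.74 ± 0.26 (5 and 1 adjusted over the list alone; list adjusted p = 0.016, and adjusted p = 0.167 with an estimated correlation).

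The remaining lists moved in part on anaerobic growth of the wild type. Not called against the aerobic pool were nikD, glpD, appC, hcr and clpB. Nickel transport rose in 4 of 6 genes (4 adjusted over the list alone; list adjusted p = 0.0657), led by nikD at 1.60 ± 0.24, and in 2 genes without wild type aerobic replicate 1 or wild type anaerobic replicate 1 or 3. Glycerol uptake fell in 2 of 6 genes and rose in 1 (2 and 1 adjusted over the list alone; list adjusted p = 0.321), with the aerobic dehydrogenase gene glpD at -1.74 ± 0.30, and fell in 4 without wild type anaerobic replicate 2. Cytochrome bd oxidases rose in 2 of 5 genes and fell in 1 (2 and 1 adjusted over the list alone; list adjusted p = 0.267), with appC at 3.36 ± 0.39, the only riser left in 5 of 6 omissions (each except wild type aerobic replicate 3). Nitric oxide genes rose in 4 of 11 (3 adjusted over the list alone; list adjusted p = 0.0585), with hcr at 3.78 ± 0.44. They rose in 1 without wild type aerobic replicate 2 or wild type anaerobic replicate 3, in 2 without wild type aerobic replicate 3 and in 7 without wild type anaerobic replicate 2. Molybdenum cofactor genes rose in 3 of 13 (3 adjusted over the list alone) and in none without wild type aerobic replicate 2 or wild type anaerobic replicate 1 or 2. Their median was -0.02 but the mean 0.15 and the camera direction were positive (adjusted p = 0.547). The median was 0.10 at equal spread and 0.07 after quantile normalisation. Iron uptake fell in 4 of 29 genes (4 adjusted over the list alone; list adjusted p = 0.103), with the ferric citrate receptor gene fecA at -4.89 ± 0.47, and fell in 10 without wild type aerobic replicate 3. For the aerobic reference set the iron list had a median of 0.03 but a mean of -0.18, and its median was negative under all 3 other scalings (-0.11, -0.16 and -0.14). Ferrous iron transport rose in 3 of 3 genes (3 adjusted over the list alone; list adjusted p = 0.115), in 1 without wild type aerobic replicate 1 and in none without wild type aerobic replicate 3 or wild type anaerobic replicate 3. Flagella and chemotaxis genes fell in 3 of 41 (0 adjusted over the list alone; list adjusted p = 0.0132, and adjusted p = 0.678 with an estimated correlation). They fell in 1 without wild type aerobic replicate 2, in 18 without wild type anaerobic replicate 2 and in none without wild type anaerobic replicate 3. Heat shock rose in 2 of 15 genes and fell in 2 (2 and 2 adjusted over the list alone; list adjusted p = 0.603), with the chaperone gene clpB at 1.64 ± 0.30, and rose in 4 without wild type aerobic replicate 3.

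The same oxygen comparison was made in the fnr mutant (n = 3 arrays per group and set). Acid resistance and trehalose genes and sodA moved strongly in the mutant too. The glutamate decarboxylase genes gadB and gadA rose by 6.34 ± 0.79 and 6.27 ± 0.85, and by 7.37 ± 0.51 and 6.56 ± 0.70 in the aerobic reference set. The trehalose genes treB and treC changed by -6.73 ± 0.45 and -6.34 ± 0.43, and sodA by -3.74 ± 0.32 (-3.98 ± 0.47 in the aerobic reference set). The TMAO reductase gene torA, controlled by the TorS-TorR system, rose by 3.27 ± 0.37 and 3.13 ± 0.46. By contrast fumB, at 0.73 ± 0.32 (adjusted p = 0.137), narG, at 0.30 ± 0.33 (adjusted p = 0.682), and nrfA, at 0.16 ± 0.28 (adjusted p = 0.84), were not called. Hydrogenases 1 and 2 rose in 12 of 20 genes (15 adjusted over the list alone), with hybO at 3.82 ± 0.37 and hybB at 3.51 ± 0.33 (list adjusted p = 5.66e-12, and adjusted p = 0.135 with an estimated correlation). Against the aerobic pool 1 of 20 rose, and hybO and hybB stood at 0.51 ± 0.30 (adjusted p = 0.448) and 1.42 ± 0.53 (adjusted p = 0.159). Acid resistance rose in 8 of 13 genes (9 adjusted over the list alone; adjusted p = 3.07e-08, and adjusted p = 0.242 with an estimated correlation). Against the aerobic pool it rose in 10 of 15 (11 adjusted over the list alone), with an adjusted p = 0.0288 with an estimated correlation. Flagella and chemotaxis genes fell in 26 of 41 (37 adjusted over the list alone; adjusted p = 1.05e-13, and adjusted p = 0.652 with an estimated correlation), with the phosphatase gene cheZ at -2.85 ± 0.63. The aerobic reference set gave a list median of 0.33 against -1.68 and 0 calls by limma. Each array left out lowered the 26 flagella calls, to 12, 5 and 7 without fnr mutant aerobic replicates 1, 2 and 3. They became 8, 17 and 3 without anaerobic replicates 1, 2 and 3. In all, 241 of 3193 genes rose and 203 fell, and 166 of 4145 rose and 51 fell in the aerobic reference set. Without centring the splits were 95 higher and 897 lower, with the median of all genes moved by -0.59. In the other set they were 87 higher and 12 lower, with a move of 0.12, and the total was 69 at equal spread, 91 after quantile normalisation and 101 in a fit of these groups alone. The count of 444 fell to 287 without fnr mutant anaerobic replicate 3. That of 217 fell to 142 without fnr mutant aerobic replicate 2 and 128 without fnr mutant anaerobic replicate 1. Genes called in both sets numbered 67 higher and 12 lower, where independent lists would share 10.2 and 2.7, and 5 had opposite signs. A test of the difference between the sets called 58 of 3189 genes.

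The strains' oxygen responses were compared as the wild-type change minus the mutant change (n = 3 arrays in each of 4 groups per set). The wild type gained more ansB, dcuB, ydfZ and fumB RNA without oxygen, with differences of 6.63 ± 0.47, 5.47 ± 0.47, 5.33 ± 0.37 and 5.03 ± 0.45. The aerobic reference set gave 3.98 ± 0.66, 3.75 ± 0.59, 3.10 ± 0.55 and 3.43 ± 0.52, where dcuB was not called at equal spread nor ydfZ without centring. It lost more RNA of aerobic enzymes, with differences of -6.97 ± 0.44 for cyoA, -4.62 ± 0.44 for sdhC and -3.67 ± 0.41 for sucA, the 2-oxoglutarate dehydrogenase gene. The latter pair gave -2.55 ± 0.47 and -2.37 ± 0.41 in the aerobic reference set. Differences were positive and called for 5 of 5 genes of nitrate reductase A and nitrate transport (5 adjusted over the list alone), with narK at 3.71 ± 0.54 and narG at 3.45 ± 0.47. They were so for 10 of 13 genes of the periplasmic nitrate reductase with cytochrome c maturation (12 adjusted over the list alone), 5 of 6 of Nrf (5 adjusted over the list alone) and 3 of 3 of formate dehydrogenase N (3 adjusted over the list alone). Fumarate respiration had 8 of 11 (8 adjusted over the list alone), and other FNR-activated genes had 9 of 12 (9 adjusted over the list alone). These 6 lists kept their calls with an estimated correlation (adjusted p = 0.0282, 0.0427, 0.02, 0.0265, 0.0282 and 0.02 in that order). Negative differences took 5 of 5 cytochrome bo oxidase genes (5 adjusted over the list alone) and 15 of 17 TCA cycle genes (15 adjusted over the list alone), and both lists were called with an estimated correlation too (adjusted p = 0.02 and 0.0427). Ribosomal protein genes had 43 of 54 with negative differences (53 adjusted over the list alone; adjusted p = 7.32e-19, and adjusted p = 0.172 with an estimated correlation), led by rplW at -2.10 ± 0.36. They had 7 without centring and 27 without wild type anaerobic replicate 3. The list median was -1.53, but -0.33 with 0 genes called by limma against the aerobic pool, and the mutant effect with oxygen, which enters this difference, had medians of -0.86 and 0.56 in the 2 sets. The genes narK, narG and cyoA were not called against the aerobic pool. Of 3188 genes, 210 had positive and 377 negative differences, and without centring, which moved the median by 0.52, 230 and 80. The total of 587 was 387 after quantile normalisation and 303 in a fit of these groups alone. It was 1085 without wild type anaerobic replicate 2, the only omission of 12 to move it by over 1.5 times. The aerobic reference set had 7 of 4144 differences positive and 27 negative (10 and 22 after quantile normalisation; median moved by -0.32 without centring). The total of 34 was 17 without centring, 20 without fnr mutant aerobic replicate 1, and 19 and 16 without wild type aerobic replicates 1 and 3.

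**Figure D1:**
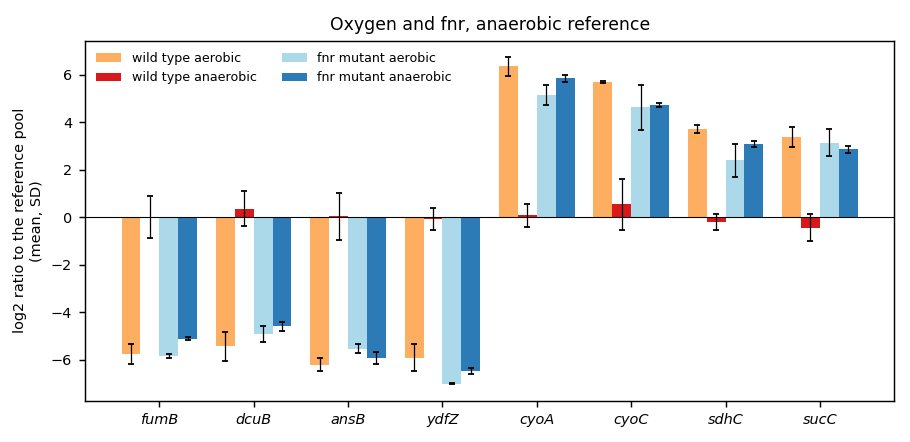
Bars give the mean log2 ratio to the anaerobic pool (SD, n = 3 arrays) of 8 genes in the wild type and the fnr mutant, each grown with and without oxygen. The mean of fumB was -5.76 with and 0.00 without oxygen in the wild type but -5.84 and -5.11 in the mutant, and that of cyoA was 6.35 and 0.08 in the wild type but 5.15 and 5.84 in the mutant.

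The fnr mutant was compared with the wild type without oxygen, where FNR is active (n = 3 arrays per group and set). The mutant held more RNA of aerobic enzymes and less RNA of anaerobic respiration in both reference sets. The oxidase genes cyoA, cyoB and cyoC were higher by 5.77 ± 0.31, 4.88 ± 0.35 and 4.19 ± 0.41, and by 2.96 ± 0.52, 2.77 ± 0.51 and 3.03 ± 0.31 in the aerobic reference set. The genes sucC and sdhC were higher by 3.31 ± 0.33 and 3.30 ± 0.31. Among the falls, ydfZ changed by -6.42 ± 0.26, ansB by -5.96 ± 0.33, fumB by -5.11 ± 0.32, dcuB by -4.95 ± 0.33 and nrfA by -4.24 ± 0.28. The matching aerobic reference values were -3.68 ± 0.39, -4.43 ± 0.47, -3.65 ± 0.37, -3.93 ± 0.42 and -2.17 ± 0.53. Lower genes included 5 of 5 of nitrate reductase A and nitrate transport (5 adjusted over the list alone), 12 of 13 of the periplasmic nitrate reductase with cytochrome c maturation (12 adjusted over the list alone) and 5 of 6 of Nrf (6 adjusted over the list alone). They also took 3 of 3 of formate dehydrogenase N (3 adjusted over the list alone), 8 of 11 of fumarate respiration (9 adjusted over the list alone) and 10 of 12 other FNR-activated genes (10 adjusted over the list alone), among them ydhV at -3.99 ± 0.41. The NADH-dependent nitrite reductase was lower in 2 of 3 genes (2 adjusted over the list alone), with nirB at -2.72 ± 0.38 (0.29 ± 0.34, adjusted p = 0.593, in the aerobic reference set). These lists kept their calls with an estimated correlation (adjusted p = 0.021, 0.0307, 0.0189, 0.0189, 0.0307, 0.0189 and 0.0338 in that order). So did the higher lists of cytochrome bo oxidase, with 5 of 5 genes (5 adjusted over the list alone; adjusted p = 0.0189), and of the TCA cycle, with 15 of 17 (15 adjusted over the list alone; adjusted p = 0.0338). Flagella and chemotaxis genes had medians of -1.24 and -2.42 in the anaerobic and aerobic reference sets, with 2 of 41 and 35 of 43 lower (0 and 38 adjusted over the list alone). Their list tests gave an adjusted p = 1.52e-06 and 5.73e-29, and an adjusted p = 0.481 and 0.0747 with an estimated correlation. The 2 calls were 30 without wild type anaerobic replicate 3 and 0 in each of the other 5 omissions, of fnr mutant anaerobic replicates 1, 2 and 3 and wild type anaerobic replicates 1 and 2. Of 3194 genes 379 were higher and 300 lower, and without centring, which moved the median by -0.22, 101 and 180. The total of 679 was 185 in a fit of these groups alone, 420 and 378 without fnr mutant anaerobic replicates 1 and 2, and 425, 1509 and 425 without wild type anaerobic replicates 1, 2 and 3. Against the aerobic pool 338 of 4146 genes were higher and 232 lower (151 and 157 at equal spread). The total of 570 was 120 without centring, 294 after quantile normalisation, 180 in a fit of these groups alone, 345 without fnr mutant anaerobic replicate 2 and 901 and 267 without wild type anaerobic replicates 1 and 2. Both sets called 149 genes higher and 57 lower, where independent lists would share 34.3 and 15.7.

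With oxygen, where FNR is known to be largely inactive, the same strains gave different pictures in the 2 reference sets (n = 3 arrays per group and set). Apart from fnr itself, at -8.43 ± 0.35 and -3.93 ± 0.51, no gene was called in both sets. In the anaerobic reference set ribosomal protein genes were lower in 26 of 54 (45 adjusted over the list alone; adjusted p = 6.8e-19, and adjusted p = 0.516 with an estimated correlation), with rplS at -1.46 ± 0.24 and rpmE at -1.37 ± 0.28. The aerobic reference set had values of 0.49 ± 0.31 (adjusted p = 0.961) and 0.57 ± 0.34 (adjusted p = 0.955) for this pair, and its list median was 0.56 against -0.86. The 26 calls were 7 without centring and 3 after quantile normalisation. They were 11, 6 and 17 without fnr mutant aerobic replicates 1, 2 and 3, and 9 and 10 without wild type aerobic replicates 1 and 2. Cytochrome bo oxidase genes were lower in 4 of 5 (5 adjusted over the list alone; adjusted p = 9.08e-05, and adjusted p = 0.516 with an estimated correlation), with a median of -1.20 that became 0.02 at equal spread, where cyoA stood at 0.15 and cyoD at 0.02. Those 4 calls were 2 without fnr mutant aerobic replicate 2 or wild type aerobic replicate 1. Against the aerobic pool flagella and chemotaxis genes were lower in 34 of 43 (42 adjusted over the list alone; median -3.28), the lowest adjusted p of the lists there at 1.87e-126, and with an estimated correlation 0.000255. The flagellin gene fliC was at -6.72 ± 0.67 (adjusted p = 5.52e-07) there and at -0.09 ± 0.83 (adjusted p = 0.966) in the anaerobic reference set, where 0 of 41 flagella genes were called by limma and the list median was -0.36. The test of the difference between the sets called 12 of 41 flagella genes and 43 of 3189 genes in all. The anaerobic reference set called 155 of 3192 genes higher and 233 lower, and 205 and 49 without centring, which moved the median by 0.26. The total of 388 was 158 at equal spread, 60 after quantile normalisation and 76 in a fit of these groups alone. It was 130 and 229 without fnr mutant aerobic replicates 2 and 3, and 133 and 187 without wild type aerobic replicates 1 and 2. In the aerobic reference set 1 of 4146 genes was higher and 62 were lower, with the median moved by -0.38 without centring.

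**Figure D2:**
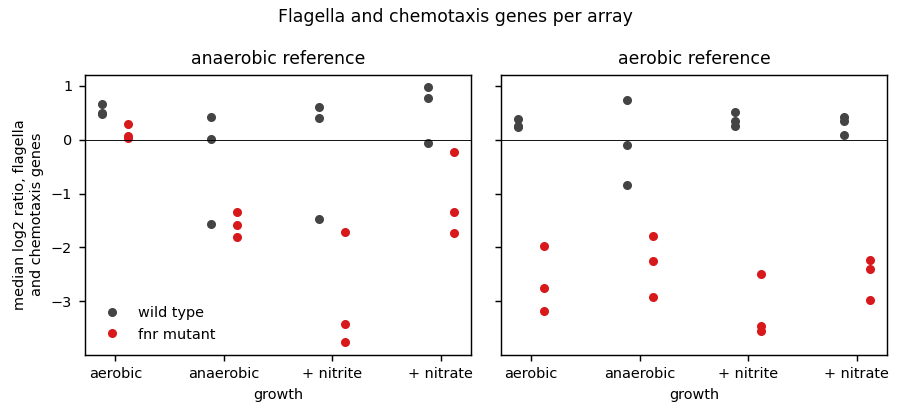
Points give the median log2 ratio to the pool of the flagella and chemotaxis genes on each array, by growth condition, for the wild type and the fnr mutant, in 1 panel per reference set (n = 3 arrays per group). Against the aerobic pool the fnr mutant arrays lay between -3.55 and -1.78 and the wild type arrays between -0.85 and 0.73, whereas against the anaerobic pool the fnr mutant arrays with oxygen lay between 0.04 and 0.29.

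Nitrate was added to anaerobic wild-type cultures (n = 3 arrays per group and set). The nitrate reductase operon, formate dehydrogenase N and nitric oxide defence genes rose, and genes of fumarate respiration, DMSO respiration and the hydrogenases fell. The catalytic subunit gene narG rose by 4.92 ± 0.33 (SE), and by 4.13 ± 0.28 in the aerobic reference set, narJ by 4.65 ± 0.40 and 4.56 ± 0.39, narH by 4.44 ± 0.38 and 3.32 ± 0.47, and narI by 4.33 ± 0.50 and 2.37 ± 0.42. The nitric oxide response genes yeaR, of unknown function, and ytfE, for the repair of iron-sulfur clusters, rose by 6.73 ± 0.57 and 5.24 ± 0.28, and in the aerobic reference set by 2.13 ± 0.39 (not called in a fit of these groups alone) and 3.61 ± 0.54. The anaerobic fumarase gene fumB changed by -4.78 ± 0.32 and -3.86 ± 0.37, the fumarate reductase gene frdB by -4.66 ± 0.33 and -2.83 ± 0.31, and the C4-dicarboxylate transporter gene dcuB by -4.48 ± 0.33 and -3.97 ± 0.42 in the 2 sets. In both sets nitrate reductase A and nitrate transport rose in 5 of 5 genes (5 adjusted over the list alone; adjusted p = 0.000798 and 2.74e-05 with an estimated correlation). In the anaerobic reference set formate dehydrogenase N rose in 3 of 3 genes (3 adjusted over the list alone), and the NADH-dependent nitrite reductase in 2 of 3 (2 adjusted over the list alone), with nirB at 3.03 ± 0.38. Nitric oxide genes rose in 8 of 11 (9 adjusted over the list alone), with the flavohaemoglobin gene hmp at 4.47 ± 0.24, and cytochrome bo oxidase in 5 of 5 (5 adjusted over the list alone), with cyoA at 3.50 ± 0.31. With an estimated correlation these 4 lists had adjusted p = 0.000997, 0.00998, 0.000798 and 0.0148. Fumarate respiration fell in 10 of 11 genes (10 adjusted over the list alone) and DMSO and TMAO reductases in 5 of 8 (5 adjusted over the list alone). Hydrogenases 1 and 2 fell in 14 of 20 (17 adjusted over the list alone). These 3 lists had adjusted p = 0.000997, 0.0392 and 0.011 with an estimated correlation. Nrf, the periplasmic nitrite reductase, fell in 4 of 6 (5 adjusted over the list alone; adjusted p = 0.000492, and adjusted p = 0.0799 with an estimated correlation). It fell in 0 by limma without centring, and in 2 without wild type nitrate replicate 3 or wild type anaerobic replicate 3. Of 3192 genes 166 rose and 123 fell, and 287 and 55 without centring, which moved the median by 0.28. The total of 289 was 76 in a fit of these groups alone, 932 and 183 without wild type anaerobic replicates 2 and 3, and 160 and 171 without wild type nitrate replicates 2 and 3. In the aerobic reference set 23 of 4147 genes rose and 23 fell, against 13 and 5 without centring, which moved the median by 0.36, 53 and 33 after quantile normalisation and 60 and 36 at equal spread. That total of 46 was 21 in a fit of these groups alone, 23 without wild type anaerobic replicate 3, and 30 and 22 without wild type nitrate replicates 2 and 3. Both sets called 16 rises and 18 falls in common, where independent lists would share 1.0 and 0.7, with no allowance for shared RNA. Not called against the aerobic pool were nirB and cyoA.

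Nitrite was added in the same way (n = 3 arrays per group and set). Genes of both periplasmic reductases, the nitrate and nitrite transporter gene narK and nitric oxide defence genes rose, and dcuB and fumB fell. The change in hmp was 5.14 ± 0.24, and 2.72 ± 0.38 in the aerobic reference set, in narK 3.50 ± 0.38 and 2.06 ± 0.28, and in the Nrf gene nrfC 2.61 ± 0.38 and 2.20 ± 0.32. The periplasmic nitrate reductase genes napC and napA rose by 2.75 ± 0.20 and 2.54 ± 0.33, and dcuB and fumB changed by -3.04 ± 0.33 and -2.79 ± 0.32. The periplasmic nitrate reductase with cytochrome c maturation rose in 12 of 13 genes (13 adjusted over the list alone), and Nrf in 6 of 6 (6 adjusted over the list alone), with nrfA at 2.55 ± 0.28. So did nitrate reductase A and nitrate transport in 5 of 5 (5 adjusted over the list alone), with narG at 1.93 ± 0.33, and the NADH-dependent nitrite reductase in 2 of 3 (3 adjusted over the list alone), with nirB at 2.78 ± 0.38. Nitric oxide genes rose in 4 of 11 (6 adjusted over the list alone), with ytfE at 4.96 ± 0.28 and the Hcp reductase gene hcr at 4.08 ± 0.44. With an estimated correlation these 5 lists had adjusted p = 0.00162, 0.00608, 0.0142, 0.00608 and 0.0309. Of 3193 genes 58 rose and 111 fell, and 43 and 16 without centring or 113 and 79 after quantile normalisation. The total of 169 was 92, 1469 and 50 without wild type anaerobic replicates 1, 2 and 3, and 297, 67 and 72 without wild type nitrite replicates 1, 2 and 3. A fit of these groups alone called 16, and not dcuB, fumB or narG. In the aerobic reference set 15 of 4147 genes rose and 2 fell, against 17 and 0 without centring, which moved the median by 0.45, and 19 and 0 at equal spread. A limma fit of these groups alone called 0 there, and in the fit of all groups 227 genes had an unadjusted p under 0.05. The 14 genes called there that both sets tested were called with the same sign in the anaerobic reference set, 12 higher and 2 lower, where independent lists would share 0.2 and 0.1, again with no such allowance. Not called against the aerobic pool were nrfA, nirB and hcr.

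Both ions were compared in the wild type as nitrate minus nitrite (n = 3 arrays per group, anaerobic reference). With nitrate the nitrate reductase operon, cytochrome bo oxidase and yeaR were higher, and Nrf, the periplasmic nitrate reductase and fumarate reductase genes were lower. The gene yeaR was higher by 5.06 ± 0.57, cyoA by 3.82 ± 0.31 and narG by 2.99 ± 0.33. In contrast nrfA differed by -3.99 ± 0.28, frdB by -4.70 ± 0.33 and napC by -2.42 ± 0.20. Nrf was lower in 6 of 6 genes (6 adjusted over the list alone), the periplasmic nitrate reductase with cytochrome c maturation in 12 of 13 (13 adjusted over the list alone), and fumarate respiration in 8 of 11 (9 adjusted over the list alone). DMSO and TMAO reductases were lower in 8 of 8 (8 adjusted over the list alone), with ynfH at -2.87 ± 0.28, and hydrogenases 1 and 2 in 12 of 20 (15 adjusted over the list alone), with the small subunit gene hybO at -2.46 ± 0.37. With an estimated correlation these 5 lists had adjusted p = 0.000156, 0.000156, 0.00141, 0.00726 and 0.0102. Nitrate reductase A and nitrate transport was higher in 4 of 5 (4 adjusted over the list alone; adjusted p = 0.0128 with an estimated correlation), but in 1 after quantile normalisation. Cytochrome bo oxidase was higher in 5 of 5 (5 adjusted over the list alone; adjusted p = 0.00395 with an estimated correlation). Of 3195 genes 82 were higher and 92 lower with nitrate, and 79 and 54 without centring, which moved the median by 0.33. The total of 174 was 275 at equal spread.

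**Figure D3:**
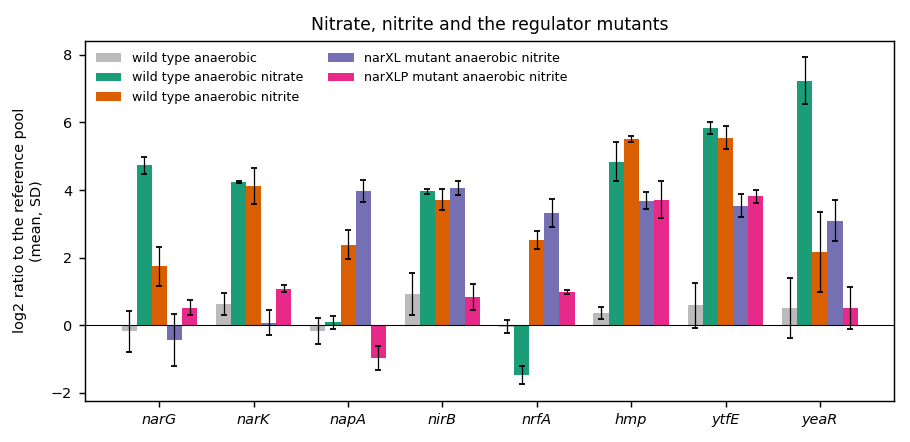
Bars give the mean log2 ratio to the anaerobic pool of 8 genes of nitrate, nitrite and nitric oxide metabolism in anaerobic cultures of the wild type alone, with nitrate and with nitrite, and of the narXL and narXLP mutants with nitrite, and error bars give the SD (n = 3 arrays per group, 4 for narXL). The Nrf gene nrfA stood at -0.04 in the wild type, -1.48 with nitrate and 2.52 with nitrite, and napA at 3.98 in the narXL mutant and -0.96 in the narXLP mutant.

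The same additions were made to the fnr mutant (n = 3 arrays per group and set). Nitric oxide defence genes rose with both ions and fumarate reductase genes fell. With nitrate yeaR rose by 7.49 ± 0.57, and by 3.14 ± 0.39 in the aerobic reference set, ytfE by 6.37 ± 0.28 and 3.23 ± 0.54, and hmp by 4.73 ± 0.24 and 3.64 ± 0.38. With nitrite the changes were 6.63 ± 0.57 and 4.30 ± 0.39 in yeaR, 6.83 ± 0.28 and 5.49 ± 0.53 in ytfE, and 5.70 ± 0.24 and 5.93 ± 0.38 in hmp. In the anaerobic reference set frdB changed by -4.17 ± 0.33 with nitrate and -3.25 ± 0.33 with nitrite. Nitric oxide genes rose in 8 of 11 with nitrate (9 adjusted over the list alone; adjusted p = 2.43e-08 with an estimated correlation) and in 11 of 11 with nitrite (11 adjusted over the list alone; adjusted p = 4.59e-08 with an estimated correlation). Fumarate respiration fell in 8 of 11 genes with nitrate (8 adjusted over the list alone; adjusted p = 6.25e-05 with an estimated correlation), and in 5 without fnr mutant nitrate replicate 2 or fnr mutant anaerobic replicate 1. With nitrite it fell in 9 of 11 (9 adjusted over the list alone; adjusted p = 0.00114 with an estimated correlation), and in 5 without fnr mutant nitrite replicate 2 or fnr mutant anaerobic replicate 1 or 2. Molybdenum cofactor genes rose in 2 of 13 with each ion (3 with nitrate and 4 with nitrite adjusted over the list alone; adjusted p = 0.0077 and 0.0179 with an estimated correlation), with moeA at 1.52 ± 0.20 and 1.41 ± 0.20, not called against the aerobic pool. With nitrate 22 of 3191 genes rose and 18 fell, and 41 and 5 without centring, which moved the median by 0.44, or 23 and 11 after quantile normalisation. With nitrite 20 of 3192 rose and 33 fell, and 27 and 7 without centring, which moved the median by 0.30, or 17 and 12 after quantile normalisation. The nitrate total of 40 was 26 without fnr mutant nitrate replicate 3. The nitrite total of 53 was 34 without fnr mutant anaerobic replicate 1 and also without 2, and 35 without fnr mutant nitrite replicate 3. In the aerobic reference set 6 genes rose and 4 fell of 4146 with nitrate, against 5 and 0 without centring or at equal spread and 5 and 2 after quantile normalisation. The median moved by 0.18 without centring. That total of 10 was 6 in a fit of these groups alone, 6 without fnr mutant anaerobic replicate 1, and 5, 6 and 21 without fnr mutant nitrate replicates 1, 2 and 3. With nitrite 7 rose and 4 fell of 4144 there, against 6 and 0 without centring, which moved the median by 0.41, and 4 and 0 at equal spread. The total of 11 was 6 after quantile normalisation, 4 in a fit of these groups alone, 6 without fnr mutant anaerobic replicate 1, and 6 and 4 without fnr mutant nitrite replicates 1 and 2. Both sets called 6 rises and 2 falls in common with each ion.

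Strain differences were tested as the wild-type change minus the change in the fnr mutant (n = 3 arrays per group, anaerobic reference). For nitrate the nitrate reductase operon and formate dehydrogenase N responded more in the wild type, and for nitrite the periplasmic reductases did, while 6 of 11 nitric oxide genes responded more to nitrite in the mutant. For nitrate the difference was 4.94 ± 0.53 in narH, 4.66 ± 0.51 in fdnG, 3.59 ± 0.54 in nirB and 3.47 ± 0.44 in cyoA, and -3.56 ± 0.39 in ynfH and -3.34 ± 0.45 in fumB. Nitrate reductase A and nitrate transport differed upward in 5 of 5 genes and formate dehydrogenase N in 3 of 3. The NADH-dependent nitrite reductase did so in 2 of 3 (5, 3 and 2 adjusted over each list alone). The lists had adjusted p = 0.000128, 0.000128 and 0.00461 with an estimated correlation. For nitrite the difference was 3.90 ± 0.54 in narK, 3.90 ± 0.38 in the Nrf gene nrfD, and 3.15 ± 0.36 in napH. It was 3.54 ± 0.56 in ompW and 3.28 ± 0.47 in frdB, from falls in the mutant (-3.88 and -3.25). It was -6.34 ± 0.98 in yoaG, -3.72 ± 0.61 in the flavorubredoxin gene norV and -3.97 ± 0.79 in its reductase gene norW. Not called were hcr, with the opposite sign at 1.98 ± 0.63 (adjusted p = 0.165), and hmp at -0.56 ± 0.34 (adjusted p = 0.407). Against the aerobic pool it was 1.796 in hcr and -3.209 in hmp, and was not tested. The periplasmic nitrate reductase with cytochrome c maturation differed upward in 12 of 13 genes and Nrf in 5 of 6. Nitric oxide genes differed downward in 6 of 11 (13, 6 and 9 adjusted over each list alone). These 3 lists had adjusted p = 0.000545, 0.00162 and 0.00197 with an estimated correlation. Of 3189 genes 35 differed upward and 13 downward for nitrate. The total of 48 was 26 without centring (median moved by -0.19), 73 at equal spread, 81 after quantile normalisation, 146 without wild type anaerobic replicate 2 and 30 without wild type nitrate replicate 2. For nitrite 33 differed upward and 9 downward, and 18 and 9 without centring (median moved by -0.31) or 35 and 18 at equal spread. The total of 42 was 26 in a fit of these groups alone and 426 without wild type anaerobic replicate 2.

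The narXL mutant, lacking NarX and NarL (n = 4 arrays), was compared with the wild type (n = 3), both with nitrite and against the anaerobic pool. Nitrate reductase genes were lower in the mutant and periplasmic nitrate reductase genes higher. Also higher were allS at 1.92 ± 0.45, ygiS at 1.87 ± 0.37, dcuB at 1.52 ± 0.31 and fumB at 1.43 ± 0.30. The transporter gene narK was at -4.05 ± 0.36, narJ at -2.54 ± 0.37, narH at -2.42 ± 0.35 and narG at -2.18 ± 0.31, and napC at 1.66 ± 0.19 and napG at 1.57 ± 0.28. Nitrate reductase A and nitrate transport was lower in 5 of 5 genes (5 adjusted over the list alone; adjusted p = 0.000271 with an estimated correlation). The periplasmic nitrate reductase with cytochrome c maturation was higher in 7 of 13 (11 adjusted over the list alone; adjusted p = 0.00531 with an estimated correlation). Nitric oxide genes were lower in 2 of 11 (3 adjusted over the list alone; adjusted p = 0.0586), ytfE at -2.01 ± 0.26 and hmp at -1.83 ± 0.22. The list mean was -0.24 and the median 0.17, which was -0.17 after quantile normalisation. Of 3198 genes 25 were higher and 14 lower, and 70 and 10 without centring, which moved the median by 0.45, 106 and 69 at equal spread, or 41 and 44 after quantile normalisation. The total of 39 was 16 without wild type nitrite replicate 3. A fit of these groups alone called 15, and not narG, narH, narJ or napG.

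The narXLP mutant, labelled as also lacking NarP, was compared with the wild type in the same way (n = 3 arrays per group). Genes of both periplasmic reductases, the nitrate reductase operon, the NADH-dependent nitrite reductase and formate dehydrogenase N were lower in it, and formate hydrogenlyase genes, dcuB and fumB were higher. Lower values were found in napH at -3.48 ± 0.26, napA at -3.34 ± 0.33, nirB at -2.88 ± 0.38, narK at -3.05 ± 0.38, nrfD at -2.37 ± 0.27 and fdnH at -2.46 ± 0.29. Higher were the regulator gene hycA at 4.73 ± 0.64, arpA at 4.08 ± 0.70 and dcuB at 3.49 ± 0.33. So were hycF at 3.32 ± 0.42, fumB at 2.92 ± 0.32, yhfX, yahL and ygjJ. The periplasmic nitrate reductase with cytochrome c maturation was lower in 13 of 13 genes and Nrf in 6 of 6. The NADH-dependent nitrite reductase and formate dehydrogenase N were lower in 3 of 3 each (13, 6, 3 and 3 adjusted over each list alone). With an estimated correlation these 4 lists had adjusted p = 0.000446, 0.0123, 0.00388 and 0.0123. Nitrate reductase A and nitrate transport was lower in 5 of 5 (5 adjusted over the list alone; adjusted p = 0.0337 with an estimated correlation), and in 3 without narXLP mutant replicate 2 or wild type nitrite replicate 3. Formate hydrogenlyase was higher in 7 of 10 (9 adjusted over the list alone; adjusted p = 1.76e-07, and adjusted p = 0.0806 with an estimated correlation). Of 3198 genes 182 were higher and 211 lower, and 584 and 39 without centring, which moved the median by 0.54. The total of 393 was 88 in a fit of these groups alone, 172 and 249 without wild type nitrite replicates 2 and 3, and 156, 179 and 719 without narXLP mutant replicates 1, 2 and 3.

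The narXLP mutant (n = 3) was set directly against the narXL mutant (n = 4), which by the labels holds narP. Genes of the periplasmic nitrate and nitrite reductases and of the NADH-dependent nitrite reductase were lower in the narXLP mutant, and formate hydrogenlyase genes were higher. The difference was -4.94 ± 0.31 in napA, -4.71 ± 0.24 in napH, -4.56 ± 0.19 in napC, -3.22 ± 0.36 in nirB and -2.33 ± 0.26 in nrfA, and 3.57 ± 0.60 in hycA and 2.52 ± 0.26 in ynfH. It was 3.58 ± 0.66 in arpA. The periplasmic nitrate reductase with cytochrome c maturation was lower in 13 of 13 genes and Nrf in 6 of 6. The NADH-dependent nitrite reductase and formate dehydrogenase N were lower in 3 of 3 each, with fdnH at -1.88 ± 0.27. Adjusted over each list alone these were 13, 6, 3 and 3. With an estimated correlation these 4 lists had adjusted p = 1.08e-06, 0.00161, 3.83e-05 and 0.00344. Formate hydrogenlyase was higher in 7 of 10 (9 adjusted over the list alone; adjusted p = 0.0256 with an estimated correlation), and in 4 without narXLP mutant replicate 2. Nitrate reductase A and nitrate transport had 0 of 5 genes called by limma (2 adjusted over the list alone; median 0.66; adjusted p = 0.00935, and adjusted p = 0.258 with an estimated correlation). Of 3202 genes 26 were higher and 53 lower, and 74 and 86 after quantile normalisation. The total of 79 was 40 without centring, 52 and 51 without narXL mutant replicates 2 and 3, and 49 and 146 without narXLP mutant replicates 1 and 3.

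**Figure D4:**
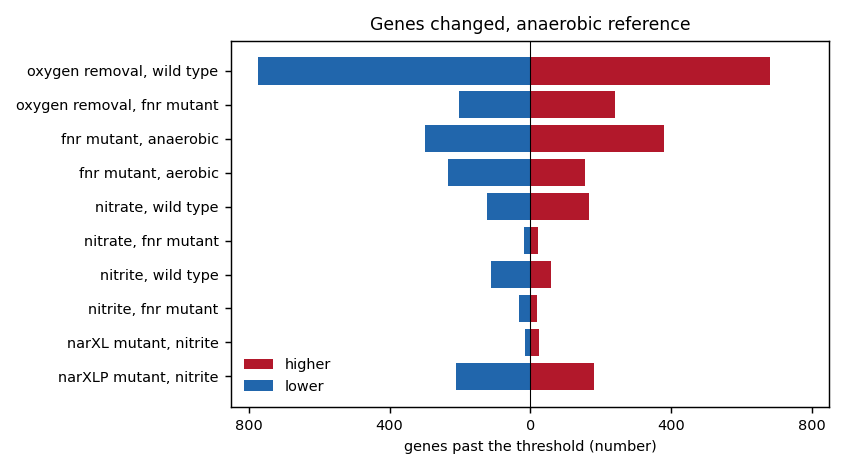
Bars to the right give the number of genes called higher and bars to the left the number called lower in 10 comparisons of the anaerobic reference set. Oxygen limitation in the wild type gave 681 genes higher and 775 lower, nitrate 166 and 123, and nitrite 58 and 111.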

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

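The explanations weighed here were tested after the results were seen. The wild type anaerobic arrays of the anaerobic reference set lay apart from each other. Independent faults of single arrays are argued against by their deviations from the group mean, which correlated across genes with those of wild type anaerobic arrays of the other set at -0.639 to 0.651, against -0.214 to 0.225 for 63 pairs of the other 7 groups. RNA or cultures that differed stay open, since a second pair at 0.602 is no separate recurrence: the deviations of 3 arrays sum to 0. No biological explanation was tested.

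Flagella and chemotaxis genes were low in every fnr mutant array of the aerobic reference set, and the aerobic mutant effect differed between the sets in 12 of 41 members. A lack of range for falls is argued against by an array of the anaerobic reference set with a list median of -3.755. Wrongly named spots are argued against by median correlations between members within groups of 0.522 in the aerobic and 0.933 in the anaerobic reference set, where 1000 random lists reached 0.098 and 0.099. Different RNA or stocks of the mutant stay open, because the 12 members show a difference and not its source.

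Of 11 nitric oxide genes, 6 rose more with nitrite in the fnr mutant (median difference -3.843), while hcr stood at 1.98 (not called). Release from FNR repression stays open, as equal release cancels in the difference that picked these 6. Their median change in the mutant without nitrite was -0.458 (SD 0.667). Against the aerobic pool 6 of 6 kept their sign (median -2.917), which argues against weak anaerobic pool signal except for norV and norW. Lower nitrite reductase levels stay open, since these 6 moved both ways in the narXLP mutant (median -0.777, SD 1.731).

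The effect of oxygen differed between wild type and fnr mutant in 587 genes of the anaerobic reference set, 28 of them called in opposite directions in the strains, and in 34 of the aerobic reference set. The effect of nitrate differed in 48 genes, fnr again among them (1.97 ± 0.49), and that of nitrite in 42. Of these 42, 1 was called in opposite directions, nrfD, named after its values were seen. The oxygen effect in the fnr mutant was called in opposite directions in the 2 sets for 5 genes, carA, carB, glcB, glnL and uraA, named after their values were seen. Their changes were 4.39 ± 0.42, 1.67 ± 0.35, -1.32 ± 0.35, 0.83 ± 0.24 and 2.81 ± 0.41 in the anaerobic reference set, and -2.60 ± 0.50, -2.60 ± 0.26, 1.93 ± 0.30, -2.10 ± 0.53 and -1.99 ± 0.44 in the other. Among the narXL mutant arrays, 1 array stood far from the other 3 in 5 of 48 values, where chance gives about 1 in 20 groups. Replicate 3 stood at -1.115 in fumB (others -1.47 to -1.42) and -2.29 in arpA (-0.635 to -0.38). Replicate 4 stood at -2.06 in narJ (-0.605 to -0.31) and 1.43 in the formate dehydrogenase N median (0.69 to 0.815), and replicate 1 at 0.3 in the ferrous iron median (-1.21 to -0.99).

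Spots without a gene name were tested apart. In the anaerobic reference set 723 passed for oxygen in the wild type, 135 in the fnr mutant, 106 for the difference, and 206 and 499 for the mutation without and with oxygen. For nitrate 67 passed in the wild type, 9 in the mutant and 17 for the difference, for nitrite 75, 42 and 11, and for nitrate minus nitrite 117. The narXL mutant gave 306, the narXLP mutant 736 and their difference 136. The other set gave 4 and 2 for oxygen in the wild type and the mutant, 8 for the mutation without oxygen and 2 for nitrate in the wild type.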

How the results depend on the processing

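Totals of changed genes that moved by over 1.5 times are given first, and the cause was not tested. At equal spread the anaerobic reference set gave 864 for oxygen in the wild type, 158 for the fnr mutation with oxygen, 275 for nitrate minus nitrite, 73 for the nitrate strain difference and 175 for the narXL mutant. The other set, with the aerobic reference, gave 605 and 69 for oxygen in the wild type and the mutant, 308 for the mutation without oxygen, 96 for nitrate in the wild type, and 5 and 4 for nitrate and nitrite in the mutant. Without centring the anaerobic reference set gave 992 for oxygen in the mutant, 281 and 254 for the mutation without and with oxygen, and 59 and 34 for nitrite in the wild type and the mutant. Strain differences were 310, 26 and 27 for oxygen, nitrate and nitrite, and the narXL and narXLP mutants gave 80 and 623, with 40 between them. The other set gave 100 and 99 for oxygen, 120 for the mutation without oxygen, 17 for the oxygen strain difference, 18 and 5 for nitrate, and 6 for nitrite in the mutant. After quantile normalisation the anaerobic reference set gave 866 for oxygen in the wild type, 60 for the mutation with oxygen, 387 and 81 for the oxygen and nitrate strain differences, 29 for nitrite in the mutant, 85 for narXL and 160 between the nar mutants. The other set gave 620 and 91 for oxygen, 294 for the mutation without oxygen, 86 for nitrate in the wild type and 6 for nitrite in the mutant. The compared groups alone, with fewer arrays, gave 408 for oxygen in the wild type, 185 and 76 for the mutation, 303 and 26 for the oxygen and nitrite strain differences, 76 and 16 for nitrate and nitrite in the wild type, and 15 and 88 for the nar mutants. In the other set they gave 130 and 101 for oxygen, 180 for the mutation without oxygen, 21 and 6 for nitrate in the wild type and the mutant, 4 for nitrite in the mutant and, by limma, 0 for nitrite in the wild type, where the fit of all groups had 227 at an unadjusted p under 0.05. Tests per spot and other handling of missing values moved none of these totals by over 1.5 times. Of 672 list tests 324 passed with the preset and 93 with an estimated correlation, and 231 by fry.

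Replicate numbers were not taken to pair the arrays, since same-numbered arrays correlated as low as -0.72 and -0.35 in the 2 sets. In the anaerobic reference set 9 of 31 arrays correlated best with their own number. In the other set 20 of 24 did, with mean correlations of 0.25, 0.08 and 0.18 for the numbers 1, 2 and 3, a hint of pairing there from the data and not from the design. With the replicate block narXLP against narXL gave 130 and the oxygen strain difference of the aerobic reference set 58, and no other total moved by over 1.5 times. Chosen after seeing the data, a fit with 1 wild type anaerobic array kept, assumed to vary like the other groups, gave 1073 for oxygen, 421 for the mutation without oxygen, 151 and 87 for nitrate and nitrite in the wild type, and 509, 34 and 49 for the oxygen, nitrate and nitrite strain differences. Also chosen after seeing the data, leaving out flagella genes in the aerobic reference set gave 22 and 520 for the mutation with and without oxygen.

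With each array left out in turn, totals of the anaerobic reference set ran from 1030 to 1896 and 287 to 366 for oxygen in the wild type and the mutant, and 378 to 1509 and 130 to 538 for the mutation without and with oxygen. They ran from 160 to 932 and 26 to 34 for nitrate, 50 to 1469 and 34 to 75 for nitrite and 121 to 177 for nitrate minus nitrite. Strain differences ran from 418 to 1085, 30 to 146 and 35 to 426, and the nar mutants from 16 to 40 and 156 to 719, with 49 to 146 between them. In the other set the ranges were 151 to 621 and 128 to 228 for oxygen, 267 to 901 and 45 to 63 for the mutation, 16 to 35 for the oxygen strain difference, 22 to 58 and 5 to 21 for nitrate, and 12 to 20 and 4 to 12 for nitrite.

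Of 548 named gene results of the anaerobic reference set, calls were kept in 3590 of 3900 fits with an array left out and 3498 of 3833 with other settings, and of 157 in the other set in 780 of 1014 and 944 of 1099. At equal spread cyoA and cyoD in the aerobic fnr comparison turned to 0.146 (adjusted p = 0.931) and 0.015 (adjusted p = 0.989), with 0 cytochrome bo oxidase genes called by limma. Of 3667 refits of 261 list counts 3076 stayed within 1.5 times, and 558 moved. The list median changed sign in 93, of which 33 had members called in the list's main direction. These 33 were, for oxygen in the wild type, molybdenum cofactor (2 called at equal spread, 1 after quantile normalisation, 0 to 3 with arrays left out), iron uptake (3 to 10 with arrays left out) and heat shock (2 to 4). In the aerobic reference set they were iron uptake (6 at equal spread and after quantile normalisation, 1 without centring, 2 to 5 with arrays left out) and glycerol uptake (0 to 2). Cytochrome bd for oxygen in the mutant had 1 without centring. Mixed-acid fermentation for the mutation without oxygen in the aerobic reference set had 0 at equal spread and after quantile normalisation by limma, and 0 to 2 with arrays left out. With nitrite, fumarate respiration had 2 to 3 with arrays left out, and in the other set 1 to 2, and 0 without centring by limma. With nitrate there, other FNR-activated genes had 0 without centring by limma. In narXL, Nrf had 2 after quantile normalisation and 0 to 1 with arrays left out, and nitric oxide genes 3 and 2 to 3, and in narXLP nitric oxide genes had 3 without centring. Signal over background was not analysed here.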

Other observations

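The splits of arrays were chosen as tests after the results were seen. Other FNR-activated genes fell with nitrate in the wild type in 7 of 12 (8 adjusted over the list alone; adjusted p = 0.0357 with an estimated correlation; n = 3 arrays per group). The outer membrane gene ompW changed by -4.46 ± 0.40, ydhV by -2.65 ± 0.41 and ydhY by -1.93 ± 0.38. The other set had 4 of 16 lower (6 adjusted over the list alone), but 0 by limma without centring, 1 without wild type nitrate replicate 3 and 2 without wild type anaerobic replicate 3. The wild-type change in ydhV minus that in the fnr mutant was -3.08 ± 0.58.

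Numbers of splits include the real one, and 10 for 3 arrays against 3 are too few for a share under 0.05. In the anaerobic reference set the real count and the highest of the other splits were 1456 and 67 for oxygen in the wild type and 444 and 1 in the fnr mutant. They were 679 and 598 for the fnr mutation without oxygen and 388 and 17 with oxygen. In the fnr mutant they were 40 and 0 for nitrate and 53 and 0 for nitrite. They were 174 and 0 for nitrate minus nitrite, and 393 and 110 for the narXLP mutant. For nitrate and nitrite in the wild type they were 289 and 1251, and 169 and 990, and 2 of 10 splits gave as many, which points to a structure of the samples. The other set gave 314 and 35, 217 and 1, 570 and 0, and 63 and 0 for the oxygen and fnr comparisons in the same order. It gave 46 and 0, and 17 and 0, for nitrate and nitrite in the wild type, and 10 and 2, and 11 and 1, in the mutant. Of 35 splits, 1 gave as many genes as narXLP against narXL (79, highest other 73), and 2 as many as the narXL mutant (39, highest other 40). The latter count leaves chance open, and so does the former, since narXL arrays may not be independent. Of 100 splits, 3 gave as many genes as the oxygen strain difference (587, highest other 857). For nitrate 12 did (48, 651), for nitrite 18 (42, 778) and for oxygen against the aerobic pool 15 (34, 519). These splits carry the oxygen, ion and strain effects into the contrast, so they decide nothing about chance.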
